A study of Homo sapiens with 6 samples.

How the data were processed

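Poly(A)-selected mRNA and small RNA were sequenced from MRC5 cells at 48 h, per the labels' protocols, from total RNA extracted with TRIzol, using Illumina TruSeq kits (the stranded kit for mRNA and the small RNA kit for miRNA). Each assay had 3 groups (control, TGF-β1, luteolin + TGF-β1) of 1 library, so that 6 libraries gave 2 main comparisons per assay: TGF-β1 over control, and luteolin + TGF-β1 over TGF-β1. Groups were assigned from the sample titles, and columns from the library names in the sample descriptions.

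Counts per Ensembl gene and counts per mature miRNA were deposited by the authors as whole numbers, per the file headers, and were used as deposited. The TPM columns are the authors' own, per the file headers, and served only to derive relative gene length. The log2 fold changes and p-values in the authors' deposited table are between single libraries, per the file headers; for all 15418 genes with a value, they equal those of edgeR's exact test with an assumed dispersion of 0.01, within a tolerance of 1e-06 in log10 p. The miRNA columns headed CPM in the deposited file are treated as a score, because they sum to 955322, 972075 and 1080939 rather than to the same total as true CPM would. Tools named in the submitters' processing notes are fastp 0.20.0, HISAT2 2.1.0, featureCounts 2.0.1 and edgeR 3.36.0, with the build hg38, and no role or order is given there. The annotation release, the strand setting of the counting and the miRNA aligner are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and genes with near-identical copies are named as uncertain.

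The mRNA table held 60623 gene IDs, of which 44020 matched a symbol and 36185 a RefSeq gene type; positions are from the RefSeq annotation of GRCh38, the assembly of hg38. The miRNA table held 1853 entries. Of the mRNA features, 21549, 20258 and 20659 had a count in the control, TGF-β1 and luteolin + TGF-β1 libraries, and of the miRNAs 1355, 1084 and 1206. Total counts ranged from 14609132 to 17876657 for mRNA and from 7533041 to 22277636 for miRNA. The 10 most abundant features took 8.09%, 11.6% and 13.4% of the mRNA counts and 63.1%, 69.1% and 69.1% of the miRNA counts. A count of 0 allows up to 3 counts, which is 0.151, 0.201 and 0.219 CPM in the mRNA libraries and 0.135, 0.370 and 0.230 CPM in the miRNA libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

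Counts were divided by the total times the TMM factor of edgeR 4.0.16 over the 3 libraries of an assay. TMM factors were 1.11, 1.02 and 0.879 for mRNA and 1.00, 1.08 and 0.929 for miRNA. A gene was eligible at 1 CPM or more, and a miRNA at 10 CPM or more, in at least 1 of the libraries compared. The exact 95% interval of each ratio is Clopper-Pearson, conditional on the sum of both counts. With 1 library per group there are no residual degrees of freedom, so no test between groups was run for any gene or miRNA apart from the recomputed test of the authors' deposited table, no p-value across genes or miRNAs is reported as a test of treatment, and a fixed rule of size was used: a ratio of at least 2-fold whose interval excludes equality. Where a library had 0 counts, the ratio was taken against the floor of 3 counts and is given as a bound.

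Before the data were examined, 33 mRNA lists and 13 miRNA lists were fixed. The mRNA lists are TGF-β/SMAD2/3 target and feedback genes, BMP/SMAD1/5 target genes, collagen chains, collagen processing and cross-linking, matrix glycoproteins and proteoglycans, contractile and myofibroblast genes, matrix proteases and their inhibitors, integrins, cytokines and NF-κB targets, interferon-stimulated genes, complement genes, NRF2 targets, aryl hydrocarbon receptor targets, the unfolded protein response, the integrated stress response with serine-glycine synthesis, heat shock, S-phase, G2/M, p53 targets and cell-cycle inhibitors, cholesterol synthesis, hypoxia and glycolysis, immediate-early and ERK feedback genes, the Wnt pathway, FOXO targets, lysosome and autophagy, lung fibroblast identity, metallothioneins, mitochondrially encoded genes, ribosomal proteins, and markers of epithelial, endothelial, leukocyte, and pericyte and smooth muscle cells. Mitochondrially encoded genes are not analysed here, as 0 of the 13 fixed symbols matched an ID with counts. The miRNA lists are pro-fibrotic and other anti-fibrotic miRNAs, the miR-29, miR-200, let-7, miR-30 and miR-181 families, the miR-17/92 and paralogous clusters, the miR-23/27/24 clusters, the arms of miR-221 and miR-222, chromosome 14q32 miRNAs, hypoxia and stress miRNAs, and miRNAs of other cell types. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 10 bins for mRNA and 5 for miRNA, as a description of these libraries.

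Genes named in the text follow a rule fixed at the same time: per comparison the 8 protein-coding genes highest and the 8 lowest by the interval bound nearest to equality, 22 anchor genes, up to 4 members per list (the most abundant and those furthest apart in either direction), the 8 genes per direction with the largest opposed ratios, and for miRNAs the 6 highest and 6 lowest and up to 4 members per list. Some genes that this rule names are not reported here. Overlaps between both comparisons share the TGF-β1 library. They were set beside overlaps of independent lists, beside 20 simulated draws of unchanged libraries with an assumed coefficient of variation of 0, 0.1, 0.2 or 0.4, and beside 20 random splits of the TGF-β1 counts.

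Counts with known changes were simulated from the mean of the 3 libraries of an assay, at the sizes of the libraries compared. For TGF-β1 against control, the rule recovered 98.5% of genes changed 3-fold and 100% of those changed 4- or 8-fold. It called 0.378% of unchanged genes, over 13412 genes. For luteolin + TGF-β1 against TGF-β1, 97.2% of 3-fold changes and 100% of 4- and 8-fold changes were recovered. Of unchanged genes 0.522% were called, over 13423 genes. For 331 and 333 simulated miRNAs in the same 2 comparisons, all 3-, 4- and 8-fold changes were recovered and 0% of the unchanged called. These simulations hold counting error only.

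Alternatives tried were total counts, DESeq2 1.42.0 size factors and the upper quartile as scalings, other filters on low values, other fold limits, an interval wholly beyond 2-fold, a prior count, thinning to the shallowest library, protein-coding genes only, merging identical miRNA entries, leaving the 5 most abundant miRNAs out of the scaling, splitting the TGF-β1 counts, and, chosen after seeing the data, the library sizes implied by the authors' miRNA columns. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.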

Results

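MRC5 cells, human lung fibroblasts, were profiled 48 h after 1 of 3 treatments: control, TGF-β1, or luteolin given together with TGF-β1. TGF-β1 is the cytokine commonly used to turn fibroblasts into matrix-producing, contractile myofibroblasts, and luteolin is a plant flavonoid. Each treatment had 1 poly(A)-selected mRNA library and 1 small RNA library, 6 libraries in all. The mRNA libraries held 17876657 counts for control, 14609132 for TGF-β1 and 15563805 for luteolin + TGF-β1, and the miRNA libraries held 22277636, 7533041 and 14044332. FN1 (ENSG00000115414), which encodes fibronectin, took the largest share of the TGF-β1 mRNA library at 3.09%, and COL1A1 (ENSG00000108821) took the largest share of the luteolin + TGF-β1 library at 2.65%. Among miRNAs, miR-29a-3p made up 15.6% of the control library, miR-16-5p 19.5% of the TGF-β1 library and miR-125b-5p 34.99% of the luteolin + TGF-β1 library. The most abundant features were looked up after their values were seen. With 1 library per group there is no replicate check: ratios compare libraries, not treatments, and each interval below is a 95% interval of the ratio on the log2 scale that covers counting error only. A gene or miRNA is called higher or lower where its ratio was at least 2-fold and that interval excluded equality.

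The comparison of TGF-β1 with control asks which transcripts differ under the fibrogenic stimulus. FN1 was 8.31-fold higher in the TGF-β1 library (log2 ratio 3.05, interval 3.04 to 3.07), ELN (ENSG00000049540), the gene for elastin, was 10.3-fold higher (interval 3.21 to 3.51 on the log2 scale), and ACTA2 (ENSG00000107796), the gene for smooth muscle actin, was 3.26-fold higher (1.71, 1.65 to 1.77). COL1A1, a chain of type I collagen, was higher with a log2 ratio of 1.07, and SMAD7, a feedback inhibitor of TGF-β signalling, was 5.96-fold higher (2.58, 2.30 to 2.85). In the opposite direction, CEMIP, which takes part in hyaluronan breakdown, went from 14412 counts to 331 and was 32.7-fold lower (-5.03, -5.19 to -4.87), and HGF, a growth factor made by fibroblasts, was 16.6-fold lower (-4.05, -4.27 to -3.84). Of 13416 eligible genes, 497 were higher and 895 lower. Positions on hg38 are chromosome 2 from 215360865 to 215436068 for FN1, chromosome 7 from 74028173 to 74069907 for ELN, chromosome 10 from 88935074 to 88991337 for ACTA2 and chromosome 17 from 50184101 to 50201631 for COL1A1; each span is the whole protein-coding gene.

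Beside these, the genes furthest above control by the bound of their interval were EGR2, an early growth response transcription factor, with a log2 ratio of 5.87 (4.30 to 8.17, on counts of 3 and 132), ACTC1, the cardiac actin gene, with 6.14 (4.25 to 9.21), DACT1 with 4.65, ESM1 with 4.89, KCNH1 with 4.60, XYLT1 with 3.81 and AMIGO2 with 3.66. CGB8 had 0 counts in control and 34 in the TGF-β1 library, but its near-identical paralogs leave that count uncertain. The genes furthest below control by that bound were SLC7A14 with a log2 ratio of -7.06 (-9.35 to -5.51), KCNF1 with -6.50, VWA5A with -4.33, TMTC1 with -4.21 and CLDN11 with -4.07, together with CEMIP and HGF. VCAM1, an adhesion molecule for leukocytes, had 127 counts in control and 0 in the TGF-β1 library, at least 31.8-fold lower against a floor of 3 counts.

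TGF-β/SMAD2/3 target and feedback genes were the list that stood furthest above control: 13 of 15 eligible members were higher and 0 lower, with a median log2 ratio of 2.06 at percentile 100 of 10000 random lists matched on expression. Its members included COMP at a log2 ratio of 3.74, the oxidase gene NOX4 at 3.16 and TGFBI, the most abundant member, at 2.60. CCN2 lay at 0.39, short of 2-fold. Matrix glycoproteins and proteoglycans had 8 of 17 members higher and 2 lower (median 0.98), with THBS2 higher at 2.38 beside ELN and FN1, and with the small proteoglycans LUM and DCN lower at -2.82 and -2.80. Contractile and myofibroblast genes had 6 of 18 higher and 2 lower (median 0.60). The cadherin CDH2 was higher at 2.48, and the 2 lower members were SYNPO2 at -1.59 and MYLK, the myosin light chain kinase, at -1.21. Among the contractile anchors, TAGLN had a log2 ratio of 1.06 and CNN1 1.47. Matrix proteases and their inhibitors had 6 of 15 higher and 2 lower (median 0.60), with ADAM19 at 3.33 and ADAM12 at 3.01 against ADAMTS1 at -2.43 and PLAU, the urokinase gene, at -2.08.

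Collagen chains were split in direction: 6 of 20 were higher and 2 lower, and the median of 0.12, at percentile 77.5, became -0.04 with no filter on low counts. COL10A1 at 3.29 and COL7A1 at 1.91 were higher, COL5A3 at -1.83 and COL15A1 at -1.25 were lower, and COL1A2 and COL3A1 had log2 ratios of 0.56 and -0.13. Collagen processing and cross-linking genes had 1 of 19 higher, P4HA3 at 2.44, and 1 lower, ADAMTS14 at -2.04, and LOX, the lysyl oxidase gene, lay at 0.99. Integrins had 2 of 13 higher and 2 lower, with ITGB3 at 1.54 against ITGA8 at -3.62 and ITGB8 at -3.34; their median was 0.67 and their mean 0.01. TNC was higher at 1.15, and POSTN had a log2 ratio of 0.92.

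Several lists lay below control. Lung fibroblast identity genes had 4 of 10 members lower and 0 higher (median -0.89, percentile 0), among them TCF21, a transcription factor of lung mesenchyme, at -2.55 and PPARG at -2.43. Complement genes had 4 of 5 lower (median -1.43, percentile 0.01), with C7 at -4.00. NRF2 targets, genes of the oxidative stress response, had 6 of 13 lower and 0 higher (median -0.92, percentile 0), including NQO1 at -1.86 (-1.94 to -1.77) and AKR1C1, whose reads can be shared with its paralogs, at -1.91; HMOX1 lay at -0.04. Interferon-stimulated genes had 6 of 13 lower and 0 higher (median -0.99, percentile 0.09), with MX1 at -3.29 on counts of 26 and 2 and IFIT1 at -2.26. Of 3 eligible aryl hydrocarbon receptor targets 2 were lower, CYP1B1 at -6.06 (-11.38 to -3.55, counts of 89 and 1) and AHRR at -2.06; CYP1A1 had 2 counts in each library and no ratio is given. Cytokines and NF-κB targets moved both ways, with 2 of 10 higher and 4 lower: PTGS2, the inducible cyclooxygenase gene, was at 3.61 and IL6 at 1.53 (1.02 to 2.06), while CCL2 was at -2.40.

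Cell-cycle lists held no called gene: 0 of 14 S-phase genes and 0 of 15 G2/M genes passed in either direction, with medians of 0.32 for each at percentiles 99.4 and 99.1. MKI67, the Ki-67 proliferation marker gene, had a log2 ratio of 0.54 (0.49 to 0.59), and CDKN1A, which encodes the p21 cell-cycle inhibitor, 0.03. Cholesterol synthesis genes had 1 of 14 higher, INSIG1 at 1.05, and a median of 0.59 at percentile 100. Immediate-early and ERK feedback genes had 5 of 17 higher and 3 lower, with ETV4 at 1.54 beside EGR2 and PHLDA1 at -1.35. BMP/SMAD1/5 target genes had 2 of 8 higher, ID3 at 1.82 and ID1 at 1.49. Of the p53 targets and cell-cycle inhibitors 1 of 11 was higher, CDKN2B at 2.36, with the list median at -0.40. Wnt pathway genes had FZD8 higher at 2.88 and 3 of 9 lower, including WNT2 at -2.17. The integrated stress response list had 1 of 15 higher, ASNS at 1.34, metallothioneins had 1 of 3, MT2A at 1.18, and FOXO targets had 1 of 8 higher and 1 lower. No member passed among 12 unfolded protein response genes, 10 heat shock genes, 14 hypoxia and glycolysis genes, 12 lysosome and autophagy genes and 20 ribosomal protein genes. Of the markers of other cell types, the epithelial keratin gene KRT19 was lower at -1.33, 1 of 7 endothelial markers (TEK) and 0 of 6 leukocyte markers were eligible, and 0 of 6 pericyte and smooth muscle markers passed.

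In the authors' deposited table, 920 genes were higher and 1187 lower in the TGF-β1 library at an adjusted p under 0.05 from edgeR's exact test, out of 15418. Those p-values equal a test with an assumed dispersion of 0.01; the same test on the same counts gave 648 genes in place of 2107 with an assumed dispersion of 0.04, and 34 with 0.16.

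**Figure D1:**
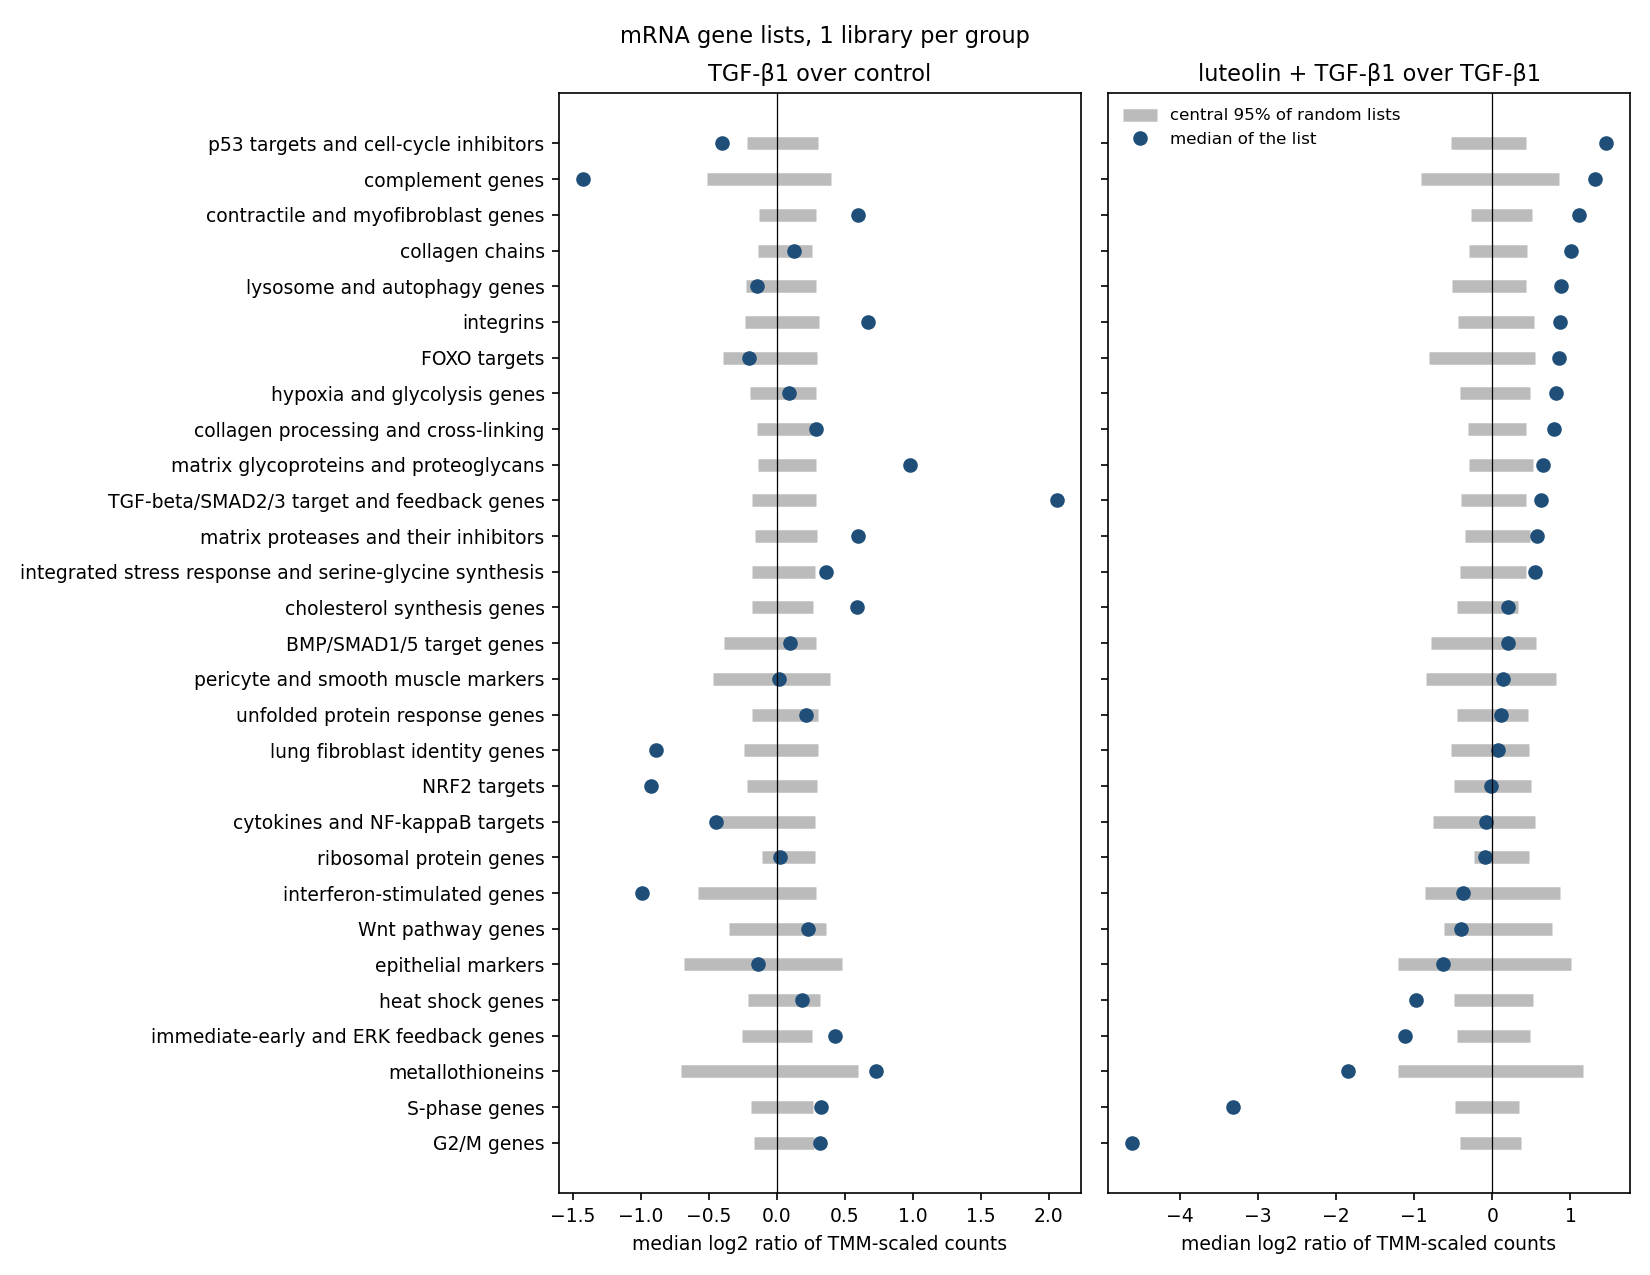
Median log2 ratio of TMM-scaled counts (x axis, a different range in each panel) for each mRNA gene list, TGF-β1 over control on the left and luteolin + TGF-β1 over TGF-β1 on the right, with 1 library per group; points are list medians and grey bars the central 95% of random lists matched on expression. The TGF-β/SMAD2/3 list lies at 2.06 on the left, and the G2/M and S-phase lists lie at -4.61 and -3.32 on the right.

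The comparison of luteolin + TGF-β1 with TGF-β1 alone asks what luteolin adds under the stimulus. Genes of cell division were lower in the luteolin + TGF-β1 library: KIF20A (ENSG00000112984), a mitotic kinesin gene, went from 2633 counts to 22 and was 110-fold lower (log2 ratio -6.78, interval -7.45 to -6.18), CDC20, an activator of the anaphase-promoting complex, was 87.7-fold lower (-6.45, -6.97 to -5.98) and MKI67 (ENSG00000148773) was 31.8-fold lower (-4.99, -5.20 to -4.79). ACTA2 was a further 6.19-fold higher than with TGF-β1 alone (2.63, 2.60 to 2.66), at 3302 CPM against 533.5, and COL1A1 had a log2 ratio of 0.81. CDKN1A (ENSG00000124762) was higher with a log2 ratio of 2.32 (2.29 to 2.35), at 3756 CPM against 751.3, while FN1 had a log2 ratio of -0.18 (-0.19 to -0.18). Of 13703 eligible genes, 1707 were higher and 2030 lower. Positions on hg38 are chromosome 5 from 138179112 to 138187723 for KIF20A, chromosome 10 from 128096659 to 128126423 for MKI67 and chromosome 6 from 36676463 to 36687332 for CDKN1A, each span being the whole protein-coding gene.

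All 14 S-phase genes were lower (median -3.32, percentile 0), with CDC45 at -4.21, GINS2 at -3.92 and the replicative helicase gene MCM7 at -3.76. All 15 G2/M genes were lower too (median -4.61, percentile 0), among them CCNB1, the cyclin B1 gene, at -5.65 and the kinase AURKA at -5.00. Other mitotic genes among those furthest below by the bound of their interval were SAPCD2 at -6.51, NEK2 at -6.10, ASPM at -5.37 and CDCA8 at -5.33. p53 targets and cell-cycle inhibitors had 7 of 11 higher and 0 lower (median 1.46, percentile 100), including the stress cytokine gene GDF15 at 2.14 and SESN1 at 2.05.

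Contractile and collagen genes lay above their level with TGF-β1 alone. Contractile and myofibroblast genes had 12 of 19 higher and 1 lower (median 1.11, percentile 100): MYH11, smooth muscle myosin, was at 4.39 (3.22 to 5.86, counts of 6 and 115), MYLK at 2.85, LMOD1 at 2.84 and TAGLN at 1.40, and DES, the desmin gene, was lower at -2.20. Collagen chains had 10 of 20 higher and 0 lower (median 1.00, percentile 100), with COL10A1 at 2.45, COL4A1 at 2.06 and COL1A2 at 1.30; COL3A1 lay at 0.96. Collagen processing and cross-linking genes had 8 of 19 higher and 1 lower, with LOXL2 at 1.72 and P4HA2 at 1.34 against LOXL1 at -1.05. Matrix glycoproteins and proteoglycans had 7 of 19 higher and 1 lower, with TNXB at 3.97, ACAN at 2.26 and DCN at 2.18, and TNC was the lower member at -1.08 (-1.13 to -1.04). TGF-β/SMAD2/3 target and feedback genes had 5 of 16 higher and 0 lower (median 0.63, percentile 99.7), including PMEPA1 at 1.75 and CCN2 at 1.05; SMAD7 lay at 0.94, ELN at 0.45 and POSTN at -0.57. Integrins had 5 of 12 higher and 1 lower, with ITGA1 at 2.62 and ITGA11, a collagen receptor subunit, at 2.18 against ITGA4 at -1.07. Matrix proteases and their inhibitors had 7 of 16 higher and 4 lower, with MMP10 at 3.33 and MMP3 at 2.96 against PLAU at -2.04 and ADAMTS1 at -1.45.

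Lists of stress and growth signalling differed in both directions. Immediate-early and ERK feedback genes had 9 of 17 lower and 1 higher (median -1.13, percentile 0): ETV4 was at -2.75 and EGR1 at -2.71, and the phosphatase gene DUSP1 was the higher member at 2.35. Heat shock genes had 5 of 10 lower and 0 higher (median -0.98, percentile 0.04), with HSPH1 at -1.53 and HSPA1A, which shares reads with HSPA1B, at -1.47. Hypoxia and glycolysis genes had 6 of 14 higher (median 0.81, percentile 99.96), with the carbonic anhydrase gene CA9 at 2.78 and VEGFA at 1.96. FOXO targets had 3 of 8 higher, with IRS2 at 1.92 and PIK3IP1 at 1.78, lysosome and autophagy genes 3 of 12, with GPNMB at 1.57 and CTSD at 1.29, and the integrated stress response list 6 of 15, with ATF3 at 1.29 and ASNS at 1.27. All 5 eligible complement genes were higher (median 1.32, percentile 99.7). Cytokines and NF-κB targets had 3 of 9 lower and 0 higher (percentile 49.5): CCL2, a monocyte chemoattractant, went from 73 counts to 0 and was at least 22.3-fold lower, ICAM1 was at -1.72 and CXCL12 at -1.18. Interferon-stimulated genes had 4 of 11 lower and 0 higher (percentile 16.9), with IFIT3 at -2.91, and 2 of 3 metallothioneins were lower, with MT1E at -2.08.

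Among NRF2 targets 1 of 13 was higher, SQSTM1 at 1.01, and 1 lower, AKR1C1 at -1.17, with NQO1 at -0.02 and HMOX1 at -0.36. The single eligible aryl hydrocarbon receptor target, TIPARP, was lower at -1.34. Lung fibroblast identity genes had 3 of 10 higher and 2 lower, with FGF7 at 2.26 against PPARG at -1.72 and HGF at -1.33. Unfolded protein response genes had 1 of 12 in each direction, cholesterol synthesis genes 2 of 14 higher, and Wnt pathway genes 1 of 9 higher and 2 lower, while 0 of 8 BMP/SMAD1/5 target genes and 0 of 20 ribosomal protein genes passed. Markers of other cell types were lower where they passed, with KRT18 at -1.76, KRT19 at -1.71, TEK at -3.52, ABCC9 at -3.18 and KCNJ8 at -2.17, apart from NOTCH3 at 1.19. By the bound of the interval, the genes furthest above TGF-β1 alone were SULF2, an extracellular sulfatase gene, at 6.83 (4.96 to 9.89, counts of 2 and 209), IQCN at 4.88, the histone genes H2BC5 at 4.67 and H2AC6 at 4.11, NXPH3 at 4.13 and SEC31B at 3.91. ZNF843 had 0 counts with TGF-β1 alone and 56 with luteolin + TGF-β1, and MAGED4 at 4.80 is uncertain because of its copy MAGED4B.

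The split of the called genes depended on scaling: 45.7% were higher with TMM, 30.8% with total counts and 58.1% with the upper quartile. In the authors' deposited table, 3078 genes were higher and 3213 lower with luteolin + TGF-β1 than with TGF-β1 alone at an adjusted p under 0.05 from edgeR's exact test with the assumed dispersion of 0.01, and a total of 6291; the same test gave 2647 genes with an assumed dispersion of 0.04 and 254 with 0.16.

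**Figure D2:**
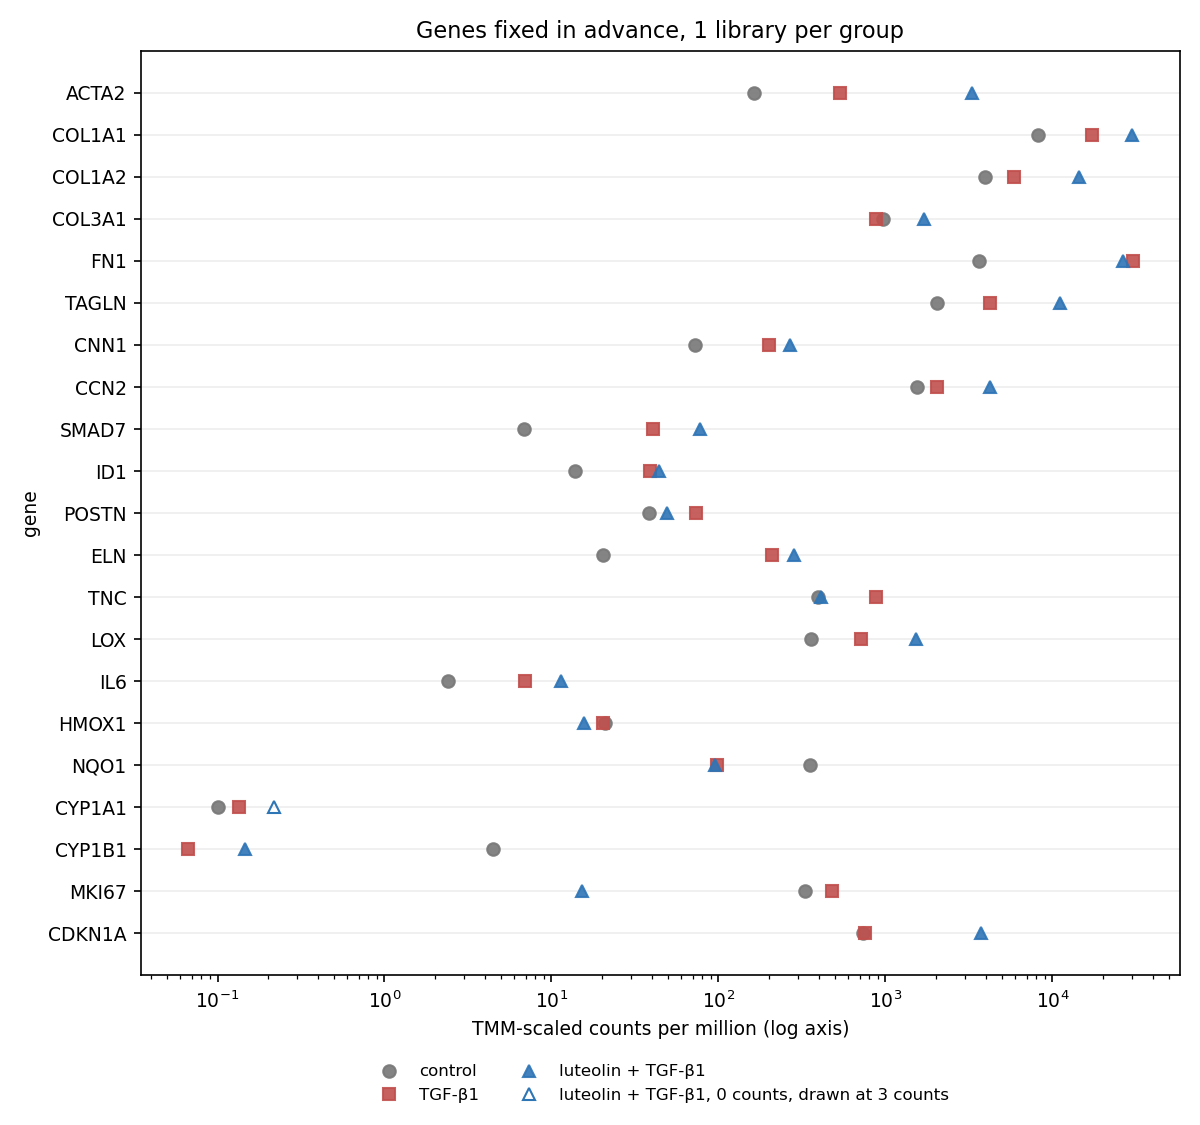
TMM-scaled CPM (log axis) of anchor genes in the control, TGF-β1 and luteolin + TGF-β1 mRNA libraries, 1 point per library. ACTA2 lies at 163.5, 533.5 and 3302 CPM in that order, and MKI67 at 331.8, 481.4 and 15.1 CPM; an open symbol marks 0 counts, drawn at the floor of 3 counts.

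Whether luteolin opposes the TGF-β1 differences was examined by overlapping both comparisons. ESM1 (ENSG00000164283), the gene for the proteoglycan endocan, which was 29.7-fold higher with TGF-β1, was 14.3-fold lower with luteolin added (log2 ratio -3.84, interval -4.93 to -2.92). MEOX1, a homeobox transcription factor gene, went from a log2 ratio of 4.32 to -3.20. Its counts were only 2, 30 and 3 in control, TGF-β1 and luteolin + TGF-β1. TNFAIP6 had ratios of 2.93 and -3.86, the Wnt ligand gene WNT7B 2.82 and -4.66, PLEK2 2.78 and -3.85 and ABTB3 2.74 and -2.74. MYO7B had 2.78 and -2.72, on counts of 7, 36 and 5 in the same order. SERF1A, at 3.64 and -4.68, is uncertain because of its copy SERF1B. In the other direction, EPAS1 (ENSG00000116016), the gene for hypoxia-inducible factor 2α, had 7816 counts in control, 543 with TGF-β1 and 4437 with luteolin + TGF-β1, with log2 ratios of -3.43 and 3.16. C7 had ratios of -4.00 and 3.45, on counts of 64, 3 and 30 in the same order. FGL2 had ratios of -3.77 and 3.32, OLR1 -3.80 and 2.95, RIPOR2 -2.73 and 2.45 and PLEKHA6 -2.86 and 2.43. HBD, at -4.93 and 3.37, shares reads with other globin genes.

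Of the 497 genes higher with TGF-β1, 144 were lower with luteolin added, 72 were higher again and 281 passed in neither direction. In the luteolin + TGF-β1 library, 282 of the 497 (56.7%) were still higher than control. ACTA2 and TAGLN were among those higher in both comparisons, and TNC was among those opposed. Of the 895 genes lower with TGF-β1, 679 were eligible in both comparisons. With luteolin added, 185 were higher, 134 were lower again and the other 576, which include those not eligible, were not called. In the luteolin + TGF-β1 library, 577 of the 895 (64.5%) were still lower than control. The counts of 282 and 577 leave out genes called on the other side of control. Of the opposed genes, 88 and 135 lay within 2-fold of control. Independent lists over the 13087 genes tested in both comparisons would share 77.1 and 63.9 genes in the opposed directions, the latter from the 679, and 46.8 and 105 in the same directions. A gene below 1 CPM with TGF-β1 was eligible in the luteolin comparison only at 1 CPM or more with luteolin added. The 679 therefore leave out genes that stayed low, which biases the 185 upward against the 63.9.

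The TGF-β1 library enters both comparisons with opposite sign, so opposed calls arise without any effect. Simulated unchanged libraries gave 3.45 and 4.45 opposed genes with counting error alone, 30.8 and 57.3 with an assumed coefficient of variation of 0.2 between cultures, and 517 and 693 with 0.4. At 0.4 the simulated libraries also gave 1699 genes higher and 1706 lower with TGF-β1, against the observed 497 and 895, and 21.2 and 20.6 genes called in the same direction in both comparisons, against 72 and 134. Splitting the TGF-β1 counts at random, so that each comparison used its own part, left 116 and 163. Across genes, which are not independent replicates, both sets of log2 ratios correlated at r = -0.197, nearer to 0 than the -0.561 to -0.516 of the simulated unchanged libraries, with a covariance of -0.147. The simulated covariance was -0.0259 with counting error alone, -0.0479, -0.115 and -0.411 with coefficients of variation of 0.1, 0.2 and 0.4, and the split libraries gave r = -0.142 and a covariance of -0.110.

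For miRNAs, the same comparison of TGF-β1 with control found more members lower than higher. miR-19a-3p, a member of the miR-17/92 cluster, went from 3381 counts to 51 and was 24.1-fold lower (log2 ratio -4.59, interval -5.02 to -4.19), and miR-335-5p went from 91416 to 1877 and was 17.7-fold lower (-4.15, -4.21 to -4.08). miR-19b-3p at -4.25, miR-450a-5p at -5.64, miR-376c-3p at -3.94 and miR-542-3p at -3.94 were also among the lowest by the bound of their interval. By the same bound, the highest were miR-1306-5p, 8.52-fold higher (3.09, 2.85 to 3.34), miR-365a-5p at 2.92, miR-671-3p at 2.53, miR-503-3p at 2.51, miR-181a-2-3p at 2.48 and miR-1307-3p at 2.47. Of 358 eligible miRNAs, 52 were higher and 133 lower.

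Among the fixed lists, 4 of 12 pro-fibrotic miRNAs were lower and 0 higher, with the list median at percentile 78.3 and 37.2% of all eligible miRNAs lower, including miR-424-5p at -2.39, miR-34a-5p at -2.33 and miR-21-5p, often studied in fibrosis, at -1.43 (-1.44 to -1.42). All 4 eligible hypoxia and stress miRNAs were lower (median -2.29, percentile 0.84), with miR-34c-5p at -2.77, the hypoxia-responsive miR-210-3p at -2.25 and miR-22-3p at -2.15 beside miR-34a-5p, which is on both lists. The chromosome 14q32 miRNAs, which come from a large imprinted cluster, had 10 of 19 lower and 0 higher (median -1.13, percentile 2.62), including miR-377-3p at -3.47. The miR-30 family had 4 of 5 lower (percentile 13.2), with miR-30b-5p at -2.58 and miR-30a-5p at -2.03, and the miR-17/92 and paralogous clusters had 4 of 9 lower and 0 higher (percentile 31.9). Members of the miR-17/92 cluster differed: miR-20a-5p lay at -3.03 and miR-18a-5p at -0.31, against miR-17-5p at 0.33 and miR-92a-3p at 0.67. In the miR-29 family, whose members target collagen transcripts, miR-29c-3p was lower at -1.86 and miR-29a-3p lay at -0.83. The miR-181 family had both eligible members higher, miR-181a-5p at 2.03 and miR-181b-5p at 1.46, and let-7i-5p was the single higher member among 9 of the let-7 family at 1.31. Other anti-fibrotic miRNAs had 2 of 7 higher, miR-486-5p at 1.31 and miR-27b-3p at 1.25, and miR-101-3p lower at -2.54. The miR-23/27/24 clusters had 2 of 6 higher and 1 lower, the arms of miR-221 and miR-222 had 1 of 4 lower, 0 of 4 eligible miRNAs of other cell types passed, and 0 of 5 members of the miR-200 family were eligible. Among the called miRNAs 28.1% were higher with TMM, against 44.8% with the upper quartile and 39.0% after thinning to equal totals; the TGF-β1 miRNA library had the lowest total.

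With luteolin + TGF-β1 against TGF-β1 alone, the miRNA differences ran the other way. miR-210-3p was 14.5-fold higher (log2 ratio 3.86, interval 3.78 to 3.94), with 1355 counts in the TGF-β1 library and 31611 with luteolin added, and miR-335-5p was 9.92-fold higher (3.31, 3.24 to 3.38). miR-19a-3p at 3.61, miR-138-5p at 3.58 and miR-19b-3p at 2.77 were also among the highest by the bound of their interval. By the same bound, the lowest were miR-503-3p, 17.0-fold lower (-4.09, -4.39 to -3.80), miR-3662 at -5.13 on counts of 87 and 4, and miR-222-5p at -3.19. miR-4483 and miR-4447, both at -3.01, had nearly the same counts, and miR-3529-3p at -2.81 had the same counts as miR-7-5p, so these 3 are uncertain. Of 342 eligible miRNAs, 115 were higher and 59 lower.

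Pro-fibrotic miRNAs had 7 of 12 higher and 2 lower (median 1.27, percentile 98.3), with miR-34a-5p at 2.57, miR-145-5p, a miRNA of contractile cells, at 2.35 and miR-214-3p at 2.04 against miR-155-5p at -2.03 and miR-199a-5p at -1.29. All 4 hypoxia and stress miRNAs were higher (median 2.24, percentile 99.6), including miR-22-3p at 1.90 and miR-34c-5p at 1.36, and all 5 miR-30 family members were higher (median 1.39, percentile 83.4). The chromosome 14q32 miRNAs had 5 of 17 higher and 2 lower (percentile 27.9), and the miR-17/92 and paralogous clusters 3 of 8 higher and 2 lower (percentile 21.2), with miR-17-5p at -1.70. In the miR-29 family, miR-29b-3p was lower at -1.16 and miR-29a-3p lay at 0.36; let-7i-5p was lower at -2.03, the single called member of 9 in its family. Other anti-fibrotic miRNAs had 2 of 7 higher, the miR-23/27/24 clusters 3 of 6 higher and 1 lower, the arms of miR-221 and miR-222 1 of 4 in each direction and the miR-181 family 0 of 2, and miR-451a, a miRNA of red blood cells, was higher at 1.40 among 4 miRNAs of other cell types.

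The same overlap was taken for miRNAs. Of the 133 miRNAs lower with TGF-β1, 114 were eligible in both comparisons and 84 were higher with luteolin added, among them miR-19a-3p, miR-335-5p and miR-210-3p, and of the 52 higher with TGF-β1, 27 were lower, among them miR-503-3p and miR-1306-5p; 1 miRNA in each direction passed the same way in both comparisons. Of the opposed miRNAs, 61 and 23 lay within 2-fold of control. In the luteolin + TGF-β1 library, 58 of the 133 were still lower than control and 14 of the 52 still higher. These counts leave out miRNAs called on the other side of control, such as miR-210-3p, higher than control at 1.60. Independent lists over the 333 miRNAs tested in both comparisons would share 37.7, from the 114, and 9.21. A miRNA below the CPM limit of eligibility with TGF-β1 was eligible in the luteolin comparison only by reaching it with luteolin added. The 114 therefore leave out miRNAs that stayed below that limit, which biases the 84 upward against the 37.7. Across miRNAs the log2 ratios correlated at r = -0.718 with a covariance of -1.53; simulated unchanged libraries gave r between -0.681 with counting error alone and -0.505.

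Simulated unchanged miRNA libraries with a shared TGF-β1 library gave a covariance of -0.00603 with counting error alone and -0.380 with an assumed coefficient of variation of 0.4. At 0.4, 17.1 simulated miRNAs were opposed from lower and 11.7 from higher. Those draws called only 41.25 miRNAs higher and 42.85 lower with TGF-β1, against the observed 52 and 133. They therefore do not show how many opposed miRNAs a larger spread between cultures would give. Splitting the TGF-β1 counts left 84.2 and 26.0 opposed miRNAs and a covariance of -1.51, but both parts come from the same library, so a peculiarity of that library enters both comparisons.

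**Figure D3:**
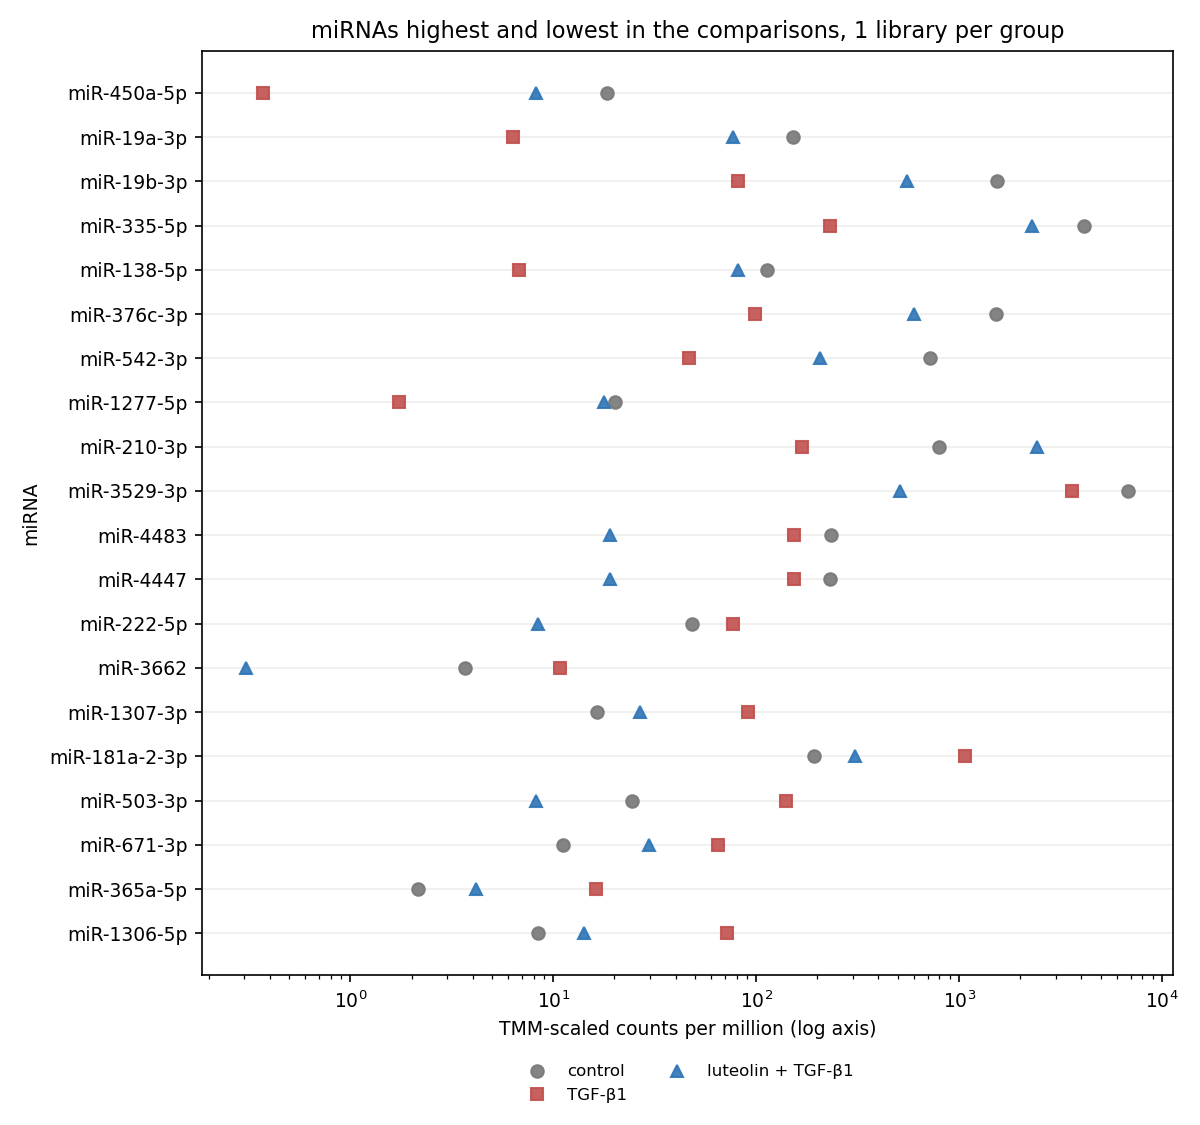
TMM-scaled CPM (log axis) of the miRNAs highest and lowest by the bound of their interval in either comparison, in the control, TGF-β1 and luteolin + TGF-β1 small RNA libraries, 1 point per library. miR-210-3p lies at 797 CPM in control, 167 with TGF-β1 and 2422 with luteolin + TGF-β1, and miR-335-5p at 4105, 231 and 2297 CPM.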

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

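The library sizes implied by the authors' miRNA columns were the alternative chosen after seeing the data. No paired analysis was possible because each group is 1 library, and no replicate could be left out or regrouped. Of the list medians, 322 values moved by less than the limit and 2 by more, and of the counts and the correlation 99 stayed within 1.5 times of their main value or within its interval and 47 did not; 1021 values of named genes and miRNAs lay within their counting interval and 590 outside it. The sign changed in 18 of 324 list values and 24 of 1611 named values, none of them called. The median of all mRNA ratios shifted by -0.12 and -0.22 in the TGF-β1 and luteolin comparisons with total counts, and by 0.17 in the luteolin comparison with the upper quartile. For miRNAs the shifts in the TGF-β1 comparison were 0.11 with total counts, 0.16 with DESeq2, 0.35 with the upper quartile, 0.26 after thinning and 0.13 with the authors' sizes, and in the luteolin comparison -0.21 with total counts and -0.13 after thinning. Counts below are, in order, higher and lower with TGF-β1, higher and lower with luteolin added, and opposed from higher and from lower.

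For mRNA these were 248, 380, 756, 1185, 49 and 60 with a filter of 10 CPM, 1112, 1653, 2914, 3332, 445 and 501 at 1.5-fold, 146, 280, 542, 752, 30 and 27 at 4-fold, and 286, 436, 922, 1201, 54 and 61 with the whole interval beyond 2-fold. For miRNA they were 131, 221, 194, 156, 81 and 128 with no filter, 17, 70, 61, 29, 12 and 44 with a filter of 100 CPM, and 12, 62, 39, 24, 5 and 22 at 4-fold. These limits and filters set how many features can pass, by construction. At 1.5-fold, 86 miRNAs were higher with TGF-β1, 89 lower with luteolin added and 49 opposed from higher. With the upper quartile, 82 miRNAs were higher with TGF-β1, as that scaling raised each log2 ratio of this comparison by 0.35. Why the upper quartile gave other library sizes was not tested. With the TGF-β1 counts split, the correlation across genes was -0.142 in place of -0.197. The parts no longer share counting error, but each also holds fewer counts, and these effects were not separated. Depth limits genes near 3 counts and the TGF-β1 miRNA library most.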

Other observations

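Both scaling tests, the miR-29 test, the cluster test and the depth test were chosen after the results were seen, and the gene length and hairpin arm tests before. The limits of the scaling test for the S-phase and G2/M genes, of the miR-29 test and of the cluster test were revised after their values had first been seen.

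Replication-dependent histone genes, a group chosen after its values were seen, went against the S-phase genes. With luteolin + TGF-β1 against TGF-β1 alone, 13 of 17 eligible members were higher and 2 lower, with a median log2 ratio of 1.89. H2AC6 went from 61 counts to 966 and was 17.3-fold higher (log2 ratio 4.11, interval 3.74 to 4.51), H2BC12 from 71 to 321 (2.30, 1.93 to 2.70), and H4C8 from 5 to 63 (3.78, 2.48 to 5.45). The 2 lower members were H2AC20 at -3.96, on 17 and 1 counts, and H2BC9 at -1.57. Several higher members, such as H4C8, were under 1 CPM with TGF-β1 alone and were eligible only through the luteolin + TGF-β1 library. That biases the 13 of 17 and the median upward. Both lower members were eligible only through the TGF-β1 library. With TGF-β1 against control 0 of 12 were higher and 5 lower. Members under 1 CPM with TGF-β1 were likewise eligible there only through control. Transcripts of these genes normally end without a poly(A) tail, so a poly(A)-selected library samples them poorly, and how much of the difference lies in transcript ends was not tested.

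Against control, the luteolin + TGF-β1 library held 1725 genes higher and 2368 lower. ACTA2 was 20.2-fold higher than in control (log2 ratio 4.34, interval 4.28 to 4.39), ELN 14.1-fold, FN1 7.33-fold and COL1A1 3.67-fold, while MKI67 was 21.9-fold lower (-4.45, -4.66 to -4.25). All 16 TGF-β/SMAD2/3 target and feedback genes were higher than in control (median 2.47). TNC and EPAS1 lay near control at 0.07 and -0.28. Of 13 NRF2 targets, 6 were lower than in control and 0 higher.

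The S-phase and G2/M genes, 29 in all, had a median log2 ratio of -3.79 with luteolin + TGF-β1 against TGF-β1 alone. Scaling between libraries does not account for it, since the value nearest to 0 among 4 scalings was -3.62. Gene length bias does not either: the median lay at percentile 0 of random lists matched on length, whose central range was -0.37 to 0.21. That luteolin lowers proliferation of these cells is a hypothesis these values are consistent with, and cell counts or DNA synthesis in replicate cultures would test it. With 1 library per group, luteolin and any other difference between these cultures, such as their density at harvest, stay open and untested, and an exchange of the TGF-β1 and luteolin + TGF-β1 libraries would turn the direction.

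Collagen and contractile genes, 39 in all, had a median log2 ratio of 1.09 in the same comparison. Scaling between libraries left at least 0.87, and gene length bias would not give percentile 100 against length-matched lists ranging from -0.18 to 0.30. Lower miR-29 is a candidate explanation, as these miRNAs target collagen transcripts, but the summed miR-29 counts had a log2 ratio of 0.18, and from -0.03 to 0.18 across scalings, which shows no clear fall of the sum and leaves activity on targets unmeasured. That sum is mostly miR-29a-3p, at 0.36. Of the 3 members 1 was lower, miR-29b-3p at -1.16, and 0 were higher, so the sum does not speak for each member. Luteolin and a denser or arrested culture stay open, as does an exchange of the TGF-β1 and luteolin + TGF-β1 libraries, while control is set apart from each by the TGF-β/SMAD2/3 genes (13 of 15 and 16 of 16 higher).

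The TGF-β1 miRNA library held 52 miRNAs higher and 133 lower than control, of 358. Part of that imbalance depends on scaling. The median log2 ratio of the eligible miRNAs was -0.52 with TMM, so the 2-fold limits did not lie evenly around it, and -0.17 with the upper quartile. With the upper quartile 82 miRNAs were higher, 44.8% of those called against 28.1% with TMM, so lower calls stayed in excess. The smaller number of reads sampled does not by itself account for most of the lower calls, because 85.7% of the 133 lower miRNAs remained after thinning to equal totals. Thinning keeps the expected ratios, so it cannot address a difference in preparation that came with the lower depth. If transcription of hairpins had changed, arms of a hairpin should move together: over 82 hairpins r was 0.39 (bootstrap 0.18 to 0.58), 46 of them (56.1%) had arms of the same sign, and of those with both arms called 16 moved the same way and 4 opposite ways; r was 0.34 (0.15 to 0.51) for luteolin + TGF-β1 over control and 0.14 (-0.05 to 0.32) for luteolin + TGF-β1 over TGF-β1. miRNAs of 10 co-transcribed clusters had a spread within clusters of 0.967 times that with permuted cluster names (0.471 to 1.26), against 0.683 (0.582 to 0.852) for luteolin + TGF-β1 over control and 1.07 (0.634 to 1.42) for luteolin + TGF-β1 over TGF-β1. Of the 40 miRNAs in these clusters 17 were of chromosome 14q32, so the ratios rest largely on that cluster. Neither value decides between a biological change and a preparation difference that acts on single sequences, which could not be tested without miRNA sequences, and a second TGF-β1 small RNA library would be the most direct check of the opposed miRNAs.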
